A study of Mus musculus with 2 samples.

How the data were processed

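Uterine RNA of CD-1 mice, from what the protocols call decidual samples, was compared between 1 library from day 8 of the first pregnancy and 1 library from day 8 of the second, day 1 being the day of the vaginal plug. Per the labels' protocols, 30 virgin females matched for age and weight were recruited, those that became pregnant raised a litter to weaning, the others served as controls, and mice in a first and in a second pregnancy were then obtained together. Whether the mice in a first pregnancy had been mated earlier without becoming pregnant is not given in the sources used here. Fetal tissue was removed under a stereomicroscope. Total RNA with an integrity number above 7.0 was purified with TRIZOL, enriched for poly(A) with oligo(dT) beads, fragmented to about 200 bp and made into libraries with a TruSeq RNA kit, per the labels' protocols.

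The values deposited by the authors are FPKM, fragment numbers scaled for transcript length and library depth, per the file headers. TopHat 1.4.0, Cufflinks 1.3.0 and the genome build mm9 are named, per the submitters' processing notes; the role of each tool and the gene annotation are not given in the sources used here. FPKM are not counts, and the authors' rule for reads that match several genes is not given in the sources used here, so genes with near-identical copies are described beside the sum of their copies. No coordinates are given, because the reference used here for names, transcript lengths and GC content (RefSeq GRCm38.p6 and GENCODE vM21) is of another build.

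Each file held 25095 rows, the same in both libraries. Of these, 1213 carried a RefSeq accession in place of a gene symbol, and 1198 of them were matched to a RefSeq gene by that accession. Rows of the same gene were summed, which gave 23972 genes, 626 of them made of more than 1 row. Rows at exactly 0 numbered 7338 in the first pregnancy and 7331 in the second. An exact 0, as for the ribosomal protein gene Rpl26, may be a failed estimate, which was not tested. Genes with an exact 0 are therefore said to be listed at 0 and have no fold. Genes of microRNAs, small nucleolar RNAs and other small RNAs, which are shorter than the fragments of the library, held 28.5% of the summed FPKM in the first pregnancy and 25.2% in the second.

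The depth was recovered from the steps between low values. Among 500 transcripts below 0.2 FPKM in both libraries, 317 ratios (63.4%) lay within 0.3% of a ratio of whole numbers up to 6, with 1 fragment in the second pregnancy worth 0.988 of 1 fragment in the first. With the transcript lengths, 98 of 193 estimates fell within 2% of a depth of 9988550 fragments in the first pregnancy, which gives 10111000 in the second. Fragment numbers estimated from this depth gave each fold a 95% Clopper-Pearson interval, for transcripts of 300 nt or longer. Lengths were those of the longest GENCODE transcript under the accession of a row or, failing that, under its gene symbol. Where that transcript is longer than the one quantified, the fragments are too many and the interval too narrow. The same lengths served the matching on length and GC content. The intervals cover counting error only, not the spread between animals or libraries. A fold and its interval are ratios of FPKM, while the log2 ratios are on the log2(FPKM + 1) scale.

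No test was made, because each group had 1 library. Genes with a mean of 1 FPKM or more were counted as higher or lower at a fixed size of 2-fold on the log2(FPKM + 1) scale, with FPKM as deposited. For 39 gene lists, the median log2 ratio of the members with a mean of 1 FPKM or more was placed as a percentile among 10000 random lists of the same size, matched on mean FPKM in 20 bins; a list stood apart under percentile 2.5 or over 97.5, and 35 lists had the 5 members required. Of 828 list genes, 825 were found in the files. These rules, the lists and the rule for named genes were set before the data were examined. The named genes were the 12 highest and 12 lowest log2 ratios, the 5 highest and 5 lowest among genes with a mean of 100 FPKM or more, in each list the 2 members of largest absolute ratio and the 2 of highest mean where members are named, and Prl8a2, Bmp2, Wnt4, Hand2, Hoxa10, Pgr and Esr1. Because the rule by size took only small RNA genes, it was repeated without them, a choice made after the data were seen, and genes with no gene name were left out of the text. Some further members of lists, such as Prl3d2, Ifit3, Krt19, Gbp2 and Lum, were also chosen after their values were seen.

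Alternatives were a pseudocount of 0.1 or 5, no filter or a mean of 5 FPKM or more, centring on the median ratio, upper-quartile scaling, equal sums, only the highest row of a gene, a size of 1.5-fold or 3-fold, the mean over members, random lists without matching, and lists without their member of largest ratio. Rows as deposited, genes without small RNAs, random lists matched on length and GC content too, near-identical copies summed, and the mean over members without small RNA genes were added after the data were seen. The match on length and GC content used 5 bins of mean FPKM in place of 20, each split into 5 bins of length and these into 3 of GC content.

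The procedure was tested on simulated data for this comparison, with the real means, 200 changed genes and 12533 genes past the filter of 1 FPKM. Of 50 genes changed 3-fold, 45 were called in the right direction, as were 45 of 50 changed 4-fold, 46 of 50 changed 8-fold and 0 of 50 changed 1.5-fold, with 14 calls among 12341 unchanged genes. A simulated step of 1.25 between the libraries was recovered as 1.25, and 96.3% of 2000 counting intervals held the true fold. Those intervals were given the simulated counts and true depths, so their share was largely set in advance. It does not test fragment numbers rebuilt from FPKM, and the depth was recovered with the same lengths that made the simulated FPKM. Of 200 lists of 20 genes drawn at random from the same genes, 4.5% stood apart, a share that the rule itself sets. All 20 lists shifted by 0.3 on the log2 scale did so. The simulated libraries held counting error alone, so none of these rates covers differences between animals or libraries. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.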

Results

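Uterine tissue of CD-1 mice, an outbred stock, was profiled by poly(A) RNA sequencing on day 8 of the first or of the second pregnancy. The labels give the tissue as uterus and the protocol as decidual samples, the decidua being what the uterine stroma forms around an implanting embryo; smooth muscle genes such as Actg2 (493 FPKM in the first pregnancy and 543 in the second) and Myh11 (80.2 and 103 FPKM) were also present. The study asked how the experience of a pregnancy bears on uterine gene expression and on decidualization, the conversion of stroma into decidua. Each group had 1 library, so no difference described here has a replicate check, and how many animals went into a library is not given in the sources used here. The summed FPKM was 900905 in the library of the first pregnancy and 813898 in that of the second. Steps between the lowest values placed the depth near 9988550 fragments in the first pregnancy and 10111000 in the second, so that 1 fragment on a transcript of 2 kb was worth 0.0556 FPKM in the first.

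Apart from small RNAs, the genes with the lowest ratios in the second pregnancy included several of secreted proteins. Spink2, a Kazal-type inhibitor of serine proteases, had 101 FPKM in the first pregnancy and 10.3 in the second, 9.76-fold lower with a 95% counting interval of 7.23 to 13.6. Cst9, of the cystatin family of cysteine protease inhibitors, was at 33.0 and 3.07 FPKM (10.7-fold lower, 6.39 to 19.9), and the secretoglobin Scgb3a1 at 20.7 and 1.95 FPKM (10.6-fold lower, 5.09 to 25.1). The interleukin 1 family member Il1f10 was at 15.3 and 3.25 FPKM, and H2-Eb1, the beta chain of the class II molecule I-E, at 13.8 and 3.03 FPKM (4.54-fold lower, 3.28 to 6.43). Bricd5 (3.72 and 0.349 FPKM) and the beta-defensin Defb25 (2.14 FPKM, listed at 0 in the second pregnancy) completed the genes of low ratio that had no near-identical copy.

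At the other end, Qrfpr, the receptor of the neuropeptide QRFP, had 3.82 FPKM in the first pregnancy and 19.03 in the second, 4.99-fold higher (3.82 to 6.72). Prl3d1, placental lactogen I of trophoblast giant cells, was at 0.405 and 4.81 FPKM, an estimated 3 and 33 fragments, and summed with its near-identical copies Prl3d2 and Prl3d3 to 1.58 and 8.86 FPKM. Cyp1a1, a monooxygenase induced through the aryl hydrocarbon receptor, was 5.38-fold higher (3.39 to 8.71) at 0.911 and 4.90 FPKM, and the chromatin protein Hmga1 was 4.59-fold higher (2.37 to 10.5) at 2.04 and 9.38 FPKM. Ghrl, which encodes ghrelin, was listed at 0 in the first pregnancy and at 3.05 FPKM in the second. Bai2 (1.57e-05 and 2.05 FPKM) met the same rule. Its value in the first pregnancy is far below 1 fragment on a transcript of 5 kb (0.0209 FPKM). It is thus no count of whole fragments, and the assignment of its reads is uncertain.

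Several genes of extreme ratio have near-identical copies or many processed copies, among which the assignment of reads is uncertain. Eif3j1 had 31.7 FPKM in the first pregnancy and 0.0143 in the second while its copy Eif3j2 had 0.0330 and 33.2, and the pair summed to 31.8 and 33.2 FPKM. The histone genes Hist2h3c2 and Hist2h3c1 exchanged places in the same manner and summed to 8.54 and 5.64 FPKM, and Pisd-ps3 and Pisd-ps1 summed to 8.05 and 10.7 FPKM. Hist2h2aa2 was listed at 0 in the first pregnancy and at 5.72 FPKM in the second, whereas its sum with Hist2h2aa1 was 47.6 and 47.8 FPKM. The ribosomal protein gene Rpl26 was at 22.1 FPKM in the first pregnancy and listed at 0 in the second, and Tmem254c, which has close neighbours of the same family, was at 8.60 and 0.645 FPKM.

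Among abundant genes, Psca, a surface antigen first described in prostate stem cells, had 471 FPKM in the first pregnancy and 201 in the second (2.34-fold lower, 2.196 to 2.499). Prl3c1, a decidual member of the prolactin family, was at 1095 and 554 FPKM (1.98-fold lower, 1.90 to 2.06), Sat1, which acetylates spermidine and spermine, at 533 and 286 FPKM, and Pdzk1ip1 at 183 and 98.3 FPKM. Thy1, a surface glycoprotein of T cells and fibroblasts, was 2.66-fold higher in the second pregnancy (2.47 to 2.87) at 64.7 and 172 FPKM. The ribosomal protein gene Rps2 followed with 112 and 236 FPKM, the implantation serine protease Prss28 with 150 and 240 FPKM, and the endoplasmic reticulum protein Rcn1 with 311 and 472 FPKM. Unlike Rps2, 39 of 41 cytosolic ribosomal protein genes were lower, and the assignment of reads to Rps2 was not tested. Atp6v0c and Atp6v0c-ps2, also selected by size, are a gene and its processed copy, and their sum was 264 FPKM in the first pregnancy and 250 in the second.

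The most extreme ratios of all belonged to genes of small RNAs, each listed at 0 in a single library. In the first pregnancy alone these were Snord19 (32216 FPKM), Mir7646 (10843), Snord65 (3742), Mir7069 (2584), Snora61 (2584), Mir6935 (1890), Snord72 (1862), Mir6960 (1550), Mir7022 (1546), Mir6999 (1542), Mir6948 (1293) and Scarna17 (1292). In the second pregnancy alone these were Mir6936 (10597 FPKM), Snord38a (2265), Mir6991 (2228), Snord91a (1840), Mir7030 (1838), Mir145 (891), Mir5132 (804), Mir6910 (710), Mir144 (709), Mir7080 (626), Mir6970 (626) and Mir6946 (496). Of the 219 small RNA genes with a mean of 1 FPKM or more, 95 were listed at 0 in exactly 1 library, against 5 of the other 12764 genes. Some genes of the same length shared nearly the same value. Mir6960, Mir7022 and Mir6999, of 61 nt, lay from 1542 to 1550 FPKM, and Mir7080 and Mir6970, of 67 nt, both at 626 FPKM. Such repeated values are what 1 or a few fragments on a very short transcript would give, so these FPKM are not read as abundance.

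**Figure D1:**
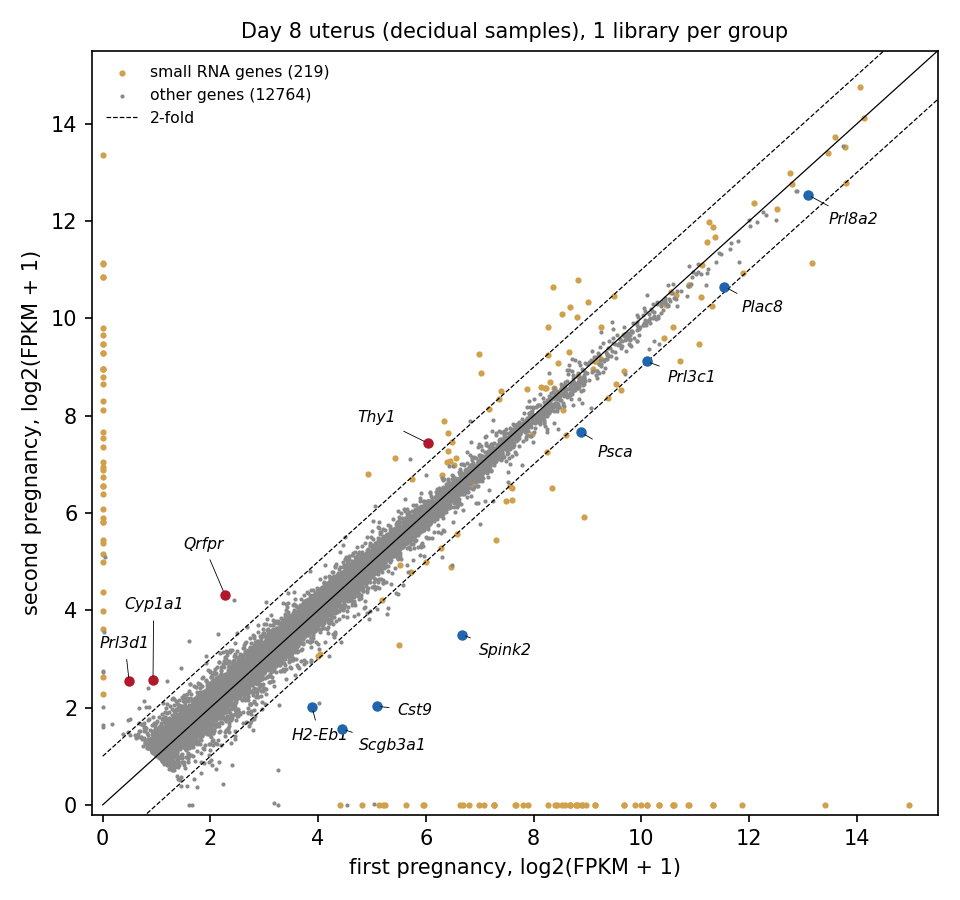
Each point is a gene with a mean of 1 FPKM or more, placed by log2(FPKM + 1) in the library of the first pregnancy (horizontal) and of the second (vertical); dashed lines mark 2-fold on this scale. Named genes lower in the second pregnancy are blue and those higher are red, and of the 219 small RNA genes (ochre) 95 lie on an axis at 0.

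In all, 12983 genes had a mean of 1 FPKM or more, and their ratios are on the log2(FPKM + 1) scale, which understates differences of low genes. At least 2-fold higher in the second pregnancy were 91 genes and at least 2-fold lower were 121; without small RNA genes the counts were 35 and 48, or 0.650% of the genes. Of these 83 genes, 77 had a transcript length that allowed a fragment estimate, and for 72 of the 77 the counting interval of the fold left out 1. Because the genes were picked by size from the same values, this was nearly set in advance and is no separate support. The 72 also include near-identical copies such as Eif3j1 and Eif3j2, whose sum hardly differed. Within 1.5-fold lay 96.6% of the genes other than small RNAs. Rescaling both libraries to the same summed FPKM moved the median log2 ratio of all genes by 0.132, from 0.02 to 0.16. It turned the balance to 114 genes higher and 101 lower, or 51 and 37 without small RNA genes. The sums include small RNA genes (256652 FPKM in the first pregnancy and 205148 in the second), which thus enter every result given with equal sums. Equal sums of the other genes alone were not tried, so small ratios that turned may depend on this choice. Left unsummed, the rows of each gene gave 142 higher and 176 lower.

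Genes of the decidual stroma were abundant in both pregnancies. Prl8a2, the decidual prolactin-related protein, was at 8732 FPKM in the first pregnancy and 5967 in the second (1.46-fold lower, 1.45 to 1.48). Bmp2, a growth factor required for decidualization, was at 178 and 212 FPKM, Wnt4 at 86.5 and 79.9 FPKM, the transcription factor Hand2 at 1004 and 900.2 FPKM, and Hoxa10 at 237 and 234 FPKM. The progesterone receptor Pgr was at 25.5 and 28.9 FPKM and the estrogen receptor Esr1 at 20.2 and 25.3 FPKM. Over the list of 30 decidualization markers, 17 were higher and 13 lower (22 and 8 with equal sums), with a median log2 ratio of 0.07 that lay at percentile 99.9 of random lists matched on mean FPKM. The mean of the same list was 0.01, and against random lists that were not matched its median lay at percentile 86.8, inside their range. The lower values of Wnt4 and Hoxa10 turned with equal sums (log2 ratios of 0.03 and 0.13).

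The prolactin family had members of both directions. Of 10 measured members, 6 were higher and 4 lower, with a median log2 ratio of 0.44 (percentile 100), but the near-identical copies Prl3d1, Prl3d2 and Prl3d3 made up 3 of the 6. With the copies summed, 4 of 8 members were higher and 4 lower, with a median of -0.04 (percentile 29.6), so the list no longer stood apart. Higher beside the Prl3d genes were Prl7a1 (0.709 and 3.42 FPKM), Prl2c2 (0.573 and 1.64 FPKM) and Prl8a9 (22.3 and 24.5 FPKM). Lower were the abundant Prl8a2 and Prl3c1, with Prl7a2 (5.68 and 3.22 FPKM) and Prl6a1 (16.3 and 14.0 FPKM).

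Interferon-induced genes were lower in the second pregnancy in 27 of 34 cases, with a median log2 ratio of -0.22 (percentile 0.0). Bst2, the antiviral protein tetherin, was at 350 and 212 FPKM (1.65-fold lower, 1.54 to 1.77), Ifi44 at 5.10 and 2.77 FPKM, Ifit3 at 5.68 and 3.19 FPKM, and Irf7, a transcription factor of the interferon response, at 85.6 and 67.8 FPKM. Gbp2 was higher in the second pregnancy, at 7.19 and 12.1 FPKM. With equal sums 21 of the 34 were lower. Of 22 listed genes of neutrophils and acute inflammation, only 9 had a mean of 1 FPKM or more. Of these 9 genes, 7 were lower, with a median of -0.28 (percentile 0.090), among them S100a9 (13.6 and 6.87 FPKM), Cxcl5 (3.23 and 1.43 FPKM) and Lcn2 (60.7 and 38.8 FPKM). Lcn2 is also in the list of estrogen-responsive genes, so the list is no measure of neutrophil number.

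Of 19 markers of uterine epithelium, 14 were lower in the second pregnancy, with a median log2 ratio of -0.18 (percentile 0.060). The surface glycoprotein Tacstd2 was at 137 and 74.5 FPKM (1.84-fold lower), Wfdc2 at 144 and 87.4 FPKM, and keratin 19 (Krt19) at 95.2 and 70.9 FPKM. The gland proteases Prss28 and Prss29 (404 and 494 FPKM) were higher, and the abundant Spink3 was at 363 and 373 FPKM. With equal sums 11 of the 19 were lower.

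Cholesterol synthesis genes were lower in 19 of 21 cases, with a median log2 ratio of -0.17 (percentile 0.0). Sc4mol, a sterol methyl oxidase, was at 32.1 and 20.6 FPKM (1.56-fold lower, 1.37 to 1.78), squalene synthase (Fdft1) at 15.6 and 11.3 FPKM, and Fdps at 72.2 and 64.1 FPKM. The abundant Dhcr24 was at 195 and 183 FPKM, an order that turned with equal sums, which left 12 of the 21 lower. Cytosolic ribosomal protein genes were lower in 39 of 41 cases with a median of -0.18 (percentile 0.44), and in 24 of 41 with equal sums. Rps20 was at 1841 and 1417 FPKM and Rplp1, which turned with equal sums, at 4919 and 4701 FPKM, while Rps2 was higher.

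Collagen and matrix genes were higher in the second pregnancy in 28 of 29 cases under each of the 4 scalings, with a median log2 ratio of 0.24 (percentile 100). Col5a1 was at 30.5 and 44.3 FPKM (1.45-fold higher, 1.38 to 1.53), elastin (Eln) at 108 and 151 FPKM, Col1a1 at 1103 and 1430 FPKM, and the matrix glycoprotein Sparc at 1537 and 1668 FPKM. Lum alone was lower, at 40.9 and 35.6 FPKM. Of 25 matrix proteases and inhibitors 18 were higher, or 22 with equal sums (percentile 91.7), with Mmp9 at 1.28 and 4.82 FPKM (3.77-fold higher, 2.62 to 5.54) and Mmp7 at 30.4 and 14.8 FPKM (2.05-fold lower, 1.66 to 2.56).

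Mitotic genes were higher in 26 of 28 cases (25 when ratios were centred), with a median log2 ratio of 0.16 (percentile 99.99). Prc1, of the central spindle, was at 17.9 and 23.9 FPKM (1.33-fold higher, 1.20 to 1.48), Kif20a at 17.4 and 23.1 FPKM, and Ube2c at 118 and 119 FPKM. Rrm2, the most abundant member, was at 1712 and 1522 FPKM. Of 26 DNA replication genes, 18 were higher and with equal sums 25 (percentile 87.7). Genes of the unfolded protein response were higher in 14 of 20 cases, or 18 with equal sums, with a median of 0.07 (percentile 98.0), Trib3 at 1.298 and 2.35 FPKM and the abundant chaperone Hspa5 at 648 and 638 FPKM. That list was inside the range of random lists without its member of largest ratio (97.4), against lists that were not matched (79.9) and with the mean (81.3). Red blood cell genes were higher in 4 of 5 cases with a median of 0.30 (percentile 99.5) but a mean of -0.04, since Hba-a2 was at 89.0 and 29.7 FPKM. Hba-a2 and its near-identical copy Hba-a1 summed to 698 and 869 FPKM.

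**Figure D2:**
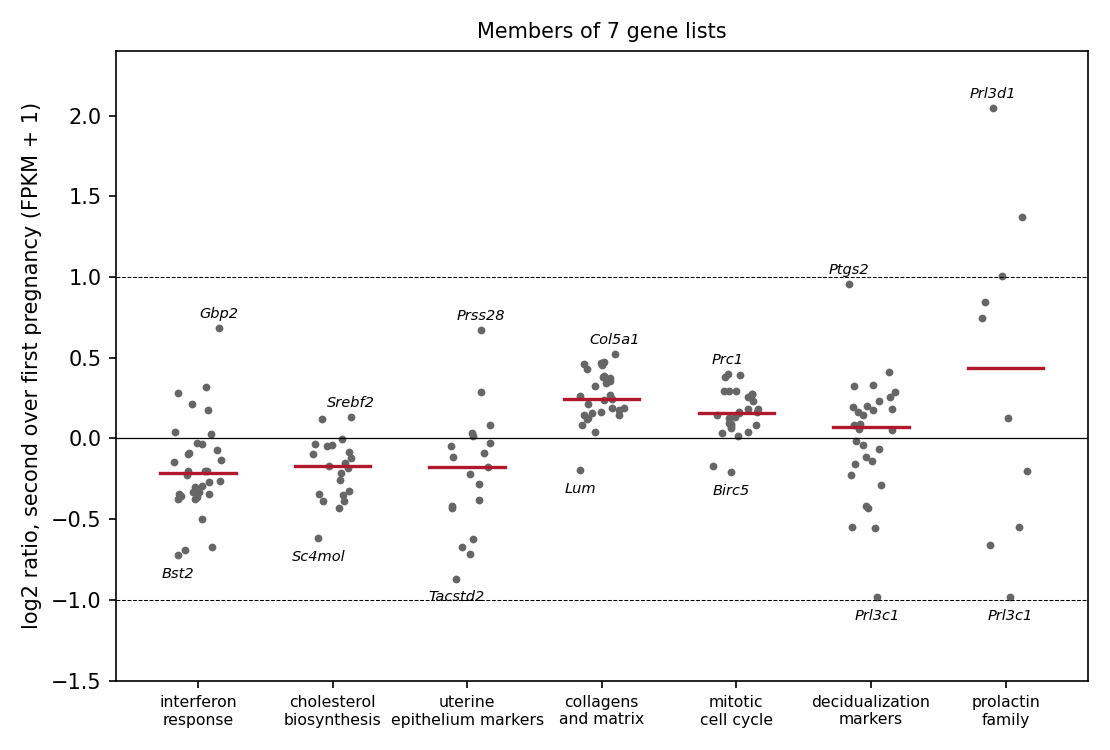
Each point is a member of 1 of 7 gene lists, placed by its log2 ratio of second over first pregnancy (FPKM + 1); red bars are list medians, dashed lines mark 2-fold, and the members of highest and lowest ratio are named. Collagen and matrix members lie above 0 in 28 of 29 cases and interferon response members below 0 in 27 of 34.

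Lists of natural killer cells, macrophages and antigen presentation lay within the range of random lists. Of 17 markers of uterine natural killer cells, 11 were lower (median -0.09, percentile 8.0), but 6 with equal sums, with the granzymes Gzmd at 491 and 459 FPKM and Gzmg at 452 and 457 FPKM. Macrophage and monocyte markers were higher in 12 of 20 cases (percentile 82.3), Lyz2 being at 78.6 and 85.0 FPKM. Class I antigen presentation genes were higher in 12 of 16 cases, or 14 with equal sums (percentile 92.7), with H2-D1 at 241 and 316 FPKM. Among 8 class II genes, 5 were higher (6 with equal sums) with a median of 0.20 (percentile 97.4) and a mean of -0.06, because H2-Eb1 was lower while H2-Aa (25.4 and 38.3 FPKM) and Cd74 (84.6 and 103 FPKM) were higher. T and B lymphocyte markers had 3 measured members, too few for a percentile and all lower, of which Cd3g was at 2.81 and 2.29 FPKM and the other two turned with equal sums.

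Hormone-related lists lay within the range of random lists, though estrogen-responsive genes left it (0.77) with the mean over members without small RNA genes. Of 16 estrogen-responsive genes 9 were lower (percentile 9.1; 7 with equal sums), including the water channel Aqp5 at 15.0 and 8.94 FPKM and lactotransferrin (Ltf) at 4.68 and 2.57 FPKM, and of 13 progesterone receptor targets 9 were lower (percentile 16.5; 5 with equal sums), including Il13ra2 at 7.05 and 3.19 FPKM. Steroid synthesis genes were higher in 7 of 11 cases (percentile 83.5), though Cyp11a1, which makes pregnenolone, was at 482 and 368 FPKM, and hormone receptors were higher in 9 of 11 (percentile 94.5). In the prostaglandin pathway 8 of 12 were lower (percentile 9.97) and 3 with equal sums, against which the inducible cyclooxygenase Ptgs2 was at 3.50 and 7.71 FPKM (2.20-fold higher, 1.81 to 2.69). Retinoic acid genes were higher in 9 of 16 cases, or 11 with equal sums (percentile 77.0), with Crabp1 at 31.4 and 56.1 FPKM.

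The remaining lists also lay within the range. Percentiles were 19.6 for endothelium and angiogenesis, 87.6 for smooth muscle, 96.7 for complement and coagulation, 96.8 for immediate early and heat shock genes, 78.3 for imprinted genes and 65.6 for the hypoxia response. They were 82.1 for glycolysis, 93.6 for oxidative phosphorylation, 84.8 for polyploidy and cell cycle arrest, 49.8 for histones, 43.1 for adipocyte markers and 94.3 for trophoblast markers. Within them, F13a1 was at 2.76 and 6.59 FPKM (2.39-fold higher, 1.88 to 3.01), the imprinted growth factor Igf2 at 3.90 and 8.00 FPKM, Vwf at 2.31 and 4.34 FPKM, Fabp4 at 833 and 462 FPKM and Plac8 at 2987 and 1613 FPKM. Platelet genes had 3 measured members (2 higher) and embryo or yolk sac markers 4 (3 higher), too few for a percentile, and Y-linked genes had none.

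**Figure D3:**
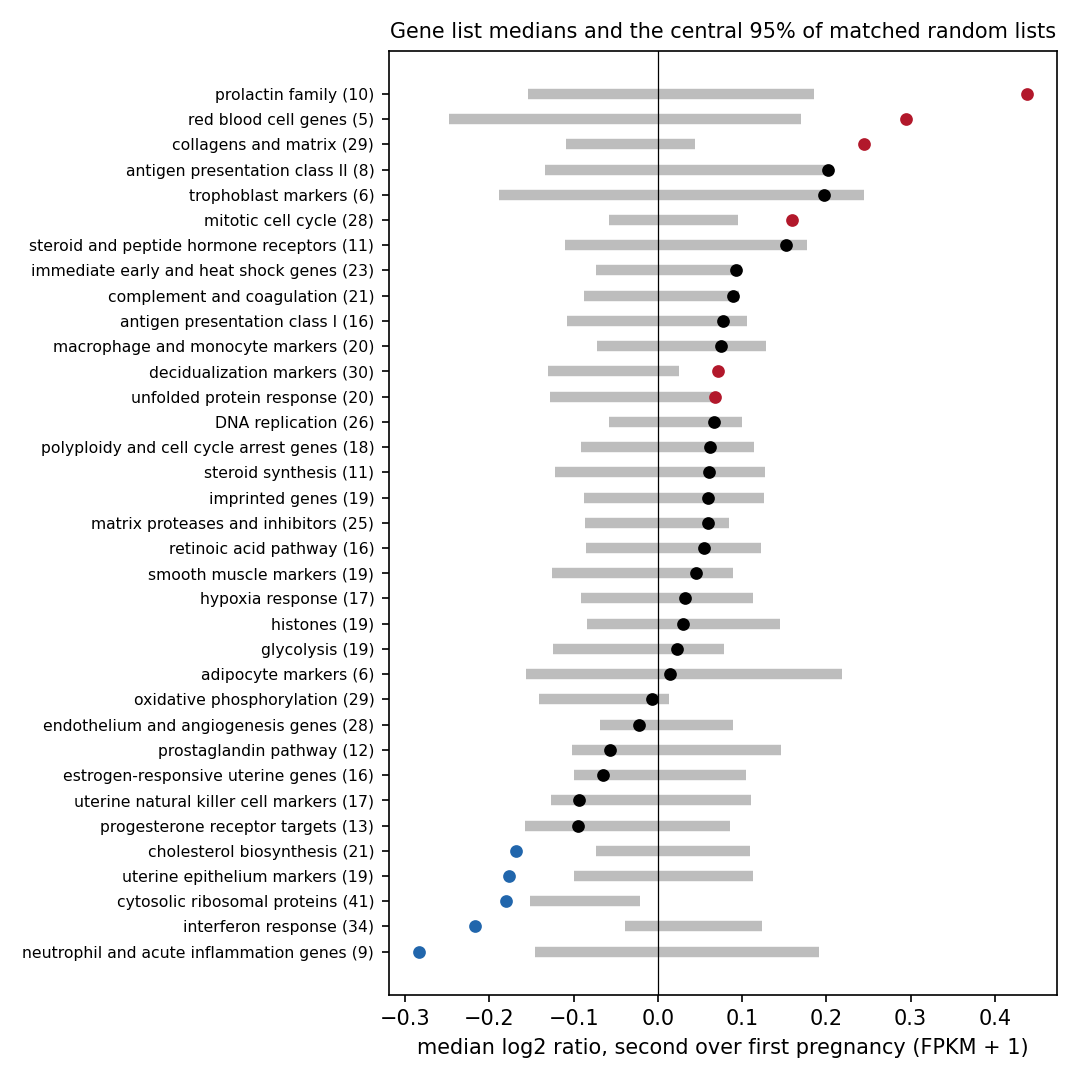
Each dot is the median log2 ratio of second over first pregnancy (FPKM + 1) of a gene list, with its number of measured members in brackets; grey bars hold the central 95% of 10000 random lists matched on mean FPKM. Medians below the bar are blue (5 lists), those above it are red (6 lists, among them the prolactin family, which left them with near-identical copies summed), and the others are black.

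In total 11 of the 35 lists stood apart from random lists, 5 lower and 6 higher. By chance 1.75 would do so at this rule if the genes of a list varied independently of each other. With near-identical copies summed 9 of 34 did, as the prolactin family lay inside the range and red blood cell genes were too few for a value. A percentile describes these libraries, not the conditions, and genes that vary together between libraries can set their list apart whatever the condition. With the mean in place of the median 1 list stood apart, that of neutrophils and acute inflammation, and 13 did so when small RNA genes were left out as well.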

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

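The tests without small RNA genes, on rows as deposited, with random lists matched on length and GC content too, with near-identical copies summed, and with the mean over members without small RNA genes were chosen only after the results were seen. Genes at least 2-fold higher numbered 146 with a pseudocount of 0.1, 281 at 1.5-fold, 59 at 3-fold, 142 with rows as deposited and 35 without small RNA genes; genes lower numbered 303 at 1.5-fold, 74 at 3-fold and 48 without small RNA genes. Among the lists, 7 of 30 stood apart at a mean of 5 FPKM or more, where the unfolded protein response was at percentile 97.365 and the prolactin family, neutrophil and red blood cell lists had fewer than 5 members left, so that no value could be given. With the mean over members 1 list stood apart; percentiles were 4.55 for cholesterol biosynthesis, 89.85 for collagens and matrix, 72.95 for decidualization, 4.83 for the interferon response, 91.68 for mitosis, 95.18 for the prolactin family, 50.23 for red blood cells, 81.26 for the unfolded protein response and 16.64 for uterine epithelium, and cytosolic ribosomal proteins crossed to 58.76. The small RNA genes drawn into random lists spread their means, for without them 13 lists stood apart, decidualization (95.32) and red blood cells (51.44) no longer did, and estrogen-responsive genes (0.77), immediate early genes (99.58), matrix proteases (98.31) and trophoblast markers (99.29) came to do so. Against random lists that were not matched, decidualization was at 86.76, the unfolded protein response at 79.94, class II genes at 98.5 and uterine natural killer cells at 2.215. Without the member of largest ratio the prolactin family was at 91.74 and the unfolded protein response at 97.44. With near-identical copies summed, which counts the Prl3d genes once, the prolactin family was at 29.57. Red blood cell genes then had too few members for a value. The log2 ratios of Eif3j1 (0.0627), Pisd-ps3 (0.37), Hba-a2 (0.32) and Hist2h3c1 (-0.52) reversed. That of Atp6v0c, under 2-fold in the report, also changed sign, from 0.63 to -0.0754. Class II genes, at 97.35 in the report, were at 97.89 with a pseudocount of 0.1, 97.53 with the highest row only, 97.62 with rows as deposited and 98.36 without small RNA genes. Over all 15 alternatives the class II list ran from percentile 16.74 to 98.5, and 10 of them kept the call of the report. Complement genes were at 98.11 with a pseudocount of 5, immediate early genes at 97.62 with no filter and oxidative phosphorylation at 99.05 when length and GC content were matched too. Apart from the small RNA genes, the summed copies and the lost members, the cause was not tested. All 35 lists gave the same call with centred ratios, upper-quartile scaling and equal sums. These scalings shift list members and random lists nearly alike, so they could hardly change a call. Directions did depend on scaling: 39 of 41 ribosomal protein genes were lower as deposited and 24 with equal sums. Of the 55 named genes at least 2-fold apart 4 changed sign under an alternative that gave them a value, which were those with summed copies. Of the 136 named genes under 2-fold 27 did, 21 of them with equal sums, and of all 191 the log2 ratio moved in 41 with a pseudocount of 0.1 and in 48 with 5. Depth limits genes near 0.167 FPKM, which is 3 fragments on 2 kb, and no paired analysis was possible because each group had 1 library.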

Other observations

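Other genes, chosen after their values were seen, also differed between the libraries. All 9 measured kallikreins, a family of secreted serine proteases, were lower in the second pregnancy (8 of 9 with equal sums), with Klk1 at 38.5 and 15.4 FPKM (2.49-fold lower, 2.00 to 3.11). The secretoglobin Scgb1a1 was at 29.9 and 13.1 FPKM and the interleukin 1 family member Il1f6 at 5.89 and 1.89 FPKM. All 6 measured members of the Serpina3 family of serine protease inhibitors were higher, also with equal sums, with Serpina3n at 32.4 and 69.9 FPKM (2.16-fold higher, 1.96 to 2.38). Of the mast cell tryptases, Tpsab1 was at 28.9 and 14.5 FPKM and Tpsb2 at 13.3 and 27.1 FPKM. Their log2 ratios were opposite and of similar size (-0.95 and 0.97), so the 2 genes nearly exchanged values. An exchange of reads between them was not tested, and neither is read as a change of its own. The microglial and macrophage receptor Trem2 was at 21.7 and 44.4 FPKM, and the hyaluronan synthase Has1 at 2.80 and 7.32 FPKM.

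Lower values in the second pregnancy were also seen for Crip1 (1278 and 713 FPKM), the metallothionein Mt4 (1125 and 659.8 FPKM) and the aspartic protease Napsa (78.0 and 33.0 FPKM). Prps2, which makes phosphoribosyl pyrophosphate for nucleotide synthesis, was at 51.0 and 137 FPKM. Of the class II genes, H2-Eb1 and H2-Ea-ps, of the I-E molecule, were at 13.8 and 3.03 FPKM and at 2.93 and 0.852 FPKM, whereas H2-Aa and H2-Ab1, of the I-A molecule, were at 25.4 and 38.3 FPKM and at 24.8 and 31.4 FPKM. Glo1, a glyoxalase gene whose copy number varies between mouse strains, was at 128 and 53.9 FPKM (2.37-fold lower, 2.10 to 2.68).

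The tests of small RNA genes, of rows that belong to 1 gene, of summed Prl3d copies, of lists matched on length and GC content and of both sources of the Prl3d genes were chosen only after the results were seen. Among genes 2-fold apart, counting error alone is argued against for genes other than small RNAs. In 100 simulated pairs of libraries at most 18 genes were 2-fold apart, against 77 observed, which include near-identical copies such as Eif3j1 and Eif3j2. The simulated fragment numbers rest on transcript lengths that may exceed those quantified, which would lower the simulated number. For genes held in more than 1 row, splitting of reads between rows is a candidate explanation, since 84.6% of the 117 rows that were 2-fold apart ended under 2-fold once summed. For small RNA genes, 43.4% were listed at 0 in exactly 1 library, and some of the same length shared nearly the same value, as 1 or a few fragments would give. With 1 library per group, counting on very short transcripts and a difference between pregnancies still cannot be told apart for them. For the others a difference between the pregnancies, between animals or between library preparations stays open and untested.

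Log2 ratios followed transcript length (Spearman rho 0.282) and GC content (rho 0.169) across 9101 genes, which are not independent replicates. Against random lists matched on length and GC content too, 10 of the lists kept their side. Mean FPKM was matched more coarsely there, in 5 bins in place of 20. Percentiles were 0.0 for cholesterol biosynthesis and the interferon response, 0.33 for uterine epithelium, 0.53 for ribosomal proteins, 1.67 for neutrophils, 98.43 for decidualization, 99.29 for the unfolded protein response, 99.99 for the prolactin family with its copies apart and 100 for collagens and for mitosis, so these trends as the whole cause are argued against. For the prolactin family, though, 3 near-identical Prl3d copies counted as separate members may account for its place, since with copies summed the list was at percentile 29.57 and no shift was left to explain. Red blood cell genes could not be matched in this way, and pregnancy number, the make-up of the dissected tissue and animal differences stay open and untested.

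The placental lactogen genes Prl3d1, Prl3d2 and Prl3d3, of trophoblast giant cells, had a summed log2 ratio of 2.41 with a pseudocount of 0.1, in tissue from which the fetal part had been removed. More embryo or yolk sac tissue cannot be told apart from a difference in giant cells, since 17 of its markers had a median log2 ratio of 0.12 but 13 of them lay under 1 FPKM, where few fragments decide a ratio. More trophoblast of every kind stays open as well, since of 13 other trophoblast markers of 0.1 to 10 FPKM 3, or 23.1% (exact interval 5.04% to 53.8%), had a log2 ratio above 0.58 and 4 had one below -0.58. That interval takes the markers as independent, which genes of 1 pair of libraries are not, so it measures no spread between animals. The 3 and the 4 all stood at 1.64 FPKM or less in both libraries, where few fragments decide a ratio. Of the trophoblast list 6 genes are also in another list and 6 had a mean of 1 FPKM or more, of the embryo list 3 and 4. Plac8 stood far above the rest of the trophoblast list, at 2987 and 1613 FPKM, the next being Tfap2c at 15.3 and 15.1 FPKM. It was therefore not read as a measure of trophoblast.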
